A study of Homo sapiens with 58 samples.

How the data were processed

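The neurons were commercial iPSC-derived cortical neurons harvested at day 14 after plating, and the brain sample was postmortem cortex, per the labels' protocols. The 58 samples fell into 9 groups by their titles: 2 neuron ATAC-seq libraries, 1 neuron and 1 brain CHD8 ChIP-seq library, 1 neuron H3K27ac ChIP-seq library, an input for each of these 3, 1 neuron RNA-seq library and 49 neuron Hi-C entries. The inputs entered no test here. The Hi-C entries were not treated as replicates, since 1 domain list stood for all of them.

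The deposited tables hold 4 lists of narrow peaks and a list of TADs as start and end positions with no score, height or p-value per region. The build is hg19, per the submitters' processing notes. These notes name BWA for ATAC-seq, ChIP-seq and Hi-C, MACS2 for ATAC-seq, and TopHat2 2.0.8 and Cufflinks for RNA-seq. The peak caller of the ChIP lists, the domain caller, the thresholds, the use of the inputs and the read depths are not given in the sources used here. The ATAC list holds only peaks common to both replicates, per the file headers, so the replicates cannot be compared. The same header says that likely artefacts were shaded grey, and the text used here carries no shading, so such peaks were kept. Expression is in FPKM computed by the authors, per the file headers, with 1 value per row. FPKM values come from an estimate rather than from whole reads, and an exact 0 can be a failed estimate, so such genes are called listed at 0. No column of values was left unmatched.

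Overlap meant at least 1 bp between half-open intervals, counted with bedtools 2.31.1 and equally by the code used for shifts. Whether starts count from 0 or 1 is not given in the sources used here, and positions are printed as listed. Chance came from 1000 circular shifts of a list within each chromosome, whose length was taken as the last listed position, with a one-sided p. Alternatives with an overlap of 0.5 of the shorter peak used 100 shifts and can give no p below 0.0099, shares inside domains, the distance profile and the chance levels of the peaks outside ATAC peaks used 200 shifts, and the width of H3K27ac peaks under shifted peaks used 100. Fisher's exact tests were two-sided, and p-values below 1e-300 are printed as that limit. For TAD edges, both ends of each domain were taken with a window of 20 kb. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9.

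The RNA table held 25227 rows. Rows whose symbol had turned into a date (28) were left out, and of the 543 symbols in more than 1 row the highest row was used, a choice made after seeing the table. Symbols were matched to current and older names in the reference gene tables, whose coordinates (assembly GRCh38.p14) were not used, and 95.6% matched. The 28 gene lists were fixed before the data were examined. Each list is described by its number of members with at least 1 FPKM, its median and the percentile of that median among 10000 random lists of the same size drawn from all symbols, which describes this library and tests no difference. KMT2B and KMT2D, both in the chromatin regulator list and KMT2D also in the intellectual disability list, were left without a value, since the table has only the older symbols MLL2 and MLL4, each shared by both genes in the reference tables. The text names, by a rule fixed before the data were examined, the 4 highest genes of each list, members below 1 FPKM among the 3 lowest of lists expected in neurons, the 10 highest genes, CHD8, and the 5 widest peaks of each list. Some genes that this rule picks are not reported here. The CHD8 lists have no widest peaks, since all are equally wide. Domains holding autism genes could not be picked without an annotation, and the 5 with the most CHD8 peaks were named in their place. The CHD gene family, the count of lists above 97.5% of random lists, the share of short non-coding RNA and the densities over domains and chromosomes were chosen after seeing the data.

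The gene annotation of hg19 was not used here, so no peak was assigned to a promoter or gene, and 3 planned comparisons that need one (location of peaks, expression by promoter state and CHD8 promoter peaks per gene list) were not run. The peak and domain lists hold no expression counts, and no model across genes was fitted. Alternatives covered the overlap rule, peak width, autosomes alone, window sizes, other null models, the FPKM threshold and the background of the random lists. The code was tested on simulated data. Of 10000 simulated peaks with 5%, 30% or 60% planted on ATAC peaks, 5.52%, 30.4% and 60.2% were found to overlap. Of 100 independent lists of 2000 peaks, 4 passed a p of 0.05 by circular shifts. The peaks of these independent lists were placed at random along the autosomes, while the real CHD8 peaks are clustered. The rate for clustered lists was therefore not tested. Of 200 simulated lists of 20 random genes, 3% lay above 97.5% of random lists, and of the same lists raised 16-fold, 83% did.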

Results

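The data described the regulatory genome of cortical neurons derived from human induced pluripotent stem cells (iPSC, reprogrammed cells that can be differentiated into other cell types), harvested at day 14 after plating, together with 1 sample of postmortem human cortex. Of the 58 samples, 2 were ATAC-seq libraries of the neurons (open chromatin, read from sites cut by a transposase), 1 was a ChIP-seq library of the neurons against acetylated lysine 27 of histone H3 (H3K27ac, a mark of active promoters and enhancers), and 1 neuron and 1 brain library were ChIP-seq against CHD8. CHD8 is a chromatin remodelling enzyme whose gene is mutated in some people with autism. Each ChIP library had its own input. The neurons also gave 1 RNA-seq library and 49 Hi-C entries, summarised as 1 list of topologically associating domains (TADs, stretches of chromosome whose parts contact each other more often than their surroundings). The peak lists held 35282 ATAC peaks found in both replicates, 39130 H3K27ac peaks, 11169 neuron CHD8 peaks and 14401 brain CHD8 peaks, and the domain list held 3132 TADs. Read depths were not given in the sources used here, so the depth behind a peak or an expression value is unknown. With 1 list per assay there was no replicate check, so the tests below describe these lists and not neurons or brains in general. Intervals are exact 95% binomial intervals that cover counting error only, and neighbouring peaks are not independent.

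The first comparison asked whether CHD8 occupied the same sites in cultured neurons and in postmortem cortex. Of the 11169 neuron CHD8 peaks, 5131 (45.9%, interval 45.0 to 46.9) overlapped a brain CHD8 peak, against 0.234% after circular shifts of the neuron list along each chromosome, a 196-fold excess. In the other direction 5030 of 14401 brain peaks (34.9%, interval 34.1 to 35.7) overlapped a neuron peak, 194-fold over shifts. The presence of an ATAC peak alone did not account for the excess. Of the 5054 ATAC peaks with neuron CHD8, 3732 (73.8%, interval 72.6 to 75.1) also had brain CHD8, while of the 30228 ATAC peaks without neuron CHD8 only 3341 (11.1%, interval 10.7 to 11.4) did. This gave an odds ratio of 22.7 (95% interval 21.1 to 24.4). A preference of both lists for the same kind of ATAC peak, such as acetylated or strong ones, could also raise it and was not separated. No shift out of 1000 reached either overlap (one-sided p = 0.001, the smallest the shifts can give), and Fisher's exact test of the ATAC peaks gave a two-sided p of at most 1e-300. Every CHD8 peak in both lists was 201 bp wide, so a stricter overlap cost many pairs: with an overlap of at least 0.5 of the peak width, 29.7% of neuron peaks were shared and the odds ratio among ATAC peaks was 14.4. Where peaks overlapped, which alone keeps centres within 201 bp, 36.1% of the centres (interval 34.8 to 37.5) lay within 50 bp of each other, against 25.1% if distances were uniform, and the median was 74 bp (quartiles 34 and 124).

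CHD8 in neurons lay mainly at acetylated chromatin. H3K27ac peaks were overlapped by 7713 of the 11169 neuron CHD8 peaks (69.1%, interval 68.2 to 69.9), 54.6-fold over the 1.26% of shifted peaks. ATAC peaks were overlapped by 5624 (50.4%, interval 49.4 to 51.3), 91.3-fold over the 0.551% of shifted peaks. Both marks were present at 41.7% of the neuron CHD8 peaks, H3K27ac alone at 27.3%, ATAC alone at 8.61% and neither at 22.3%. Of the brain CHD8 peaks, 53.2% (interval 52.4 to 54.1) lay at neuronal ATAC peaks and 58.2% (interval 57.4 to 59.1) at neuronal H3K27ac peaks, the latter a smaller share than in the neuron list. The shares of each CHD8 list at ATAC peaks and at H3K27ac peaks lay above every one of the 1000 shifts (p = 0.001), and the split by both marks was not set against shifts. The share of neuron CHD8 peaks at ATAC peaks was 25.8% when only ATAC peaks of at least the median width were kept, which leaves about 0.5 of that list.

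CHD8 peaks found in both lists lay at neuronal ATAC and H3K27ac peaks more often than those found in 1 list. Both marks were measured in neurons only, so the chromatin of brain-only peaks in the cortex is unknown. With no score or depth, peaks of 1 list cannot be told from peaks too weak to be called in the other. Of the 5131 shared neuron CHD8 peaks, 75.6% (interval 74.4 to 76.8) lay at an ATAC peak and 84.5% (interval 83.5 to 85.5) at an H3K27ac peak. Of the 6038 peaks found in neurons only, 28.9% (interval 27.8 to 30.1) and 55.9% (interval 54.7 to 57.2) did. Counted in the brain list, 77.4% of the 5030 shared peaks and 40.3% of the 9371 brain-only peaks lay at neuronal ATAC peaks, and 83.2% and 44.9% at neuronal H3K27ac peaks. Sites with neither neuronal mark were rare among shared peaks, 3.37% of the neuron list and 3.02% of the brain list, and frequent among peaks of 1 tissue, 38.4% of the neuron-only and 40.9% of the brain-only peaks. The odds ratios of shared against neuron-only peaks were 7.61 (6.98 to 8.29) for ATAC and 4.29 (3.91 to 4.70) for H3K27ac, and those of shared against brain-only peaks were 5.09 (4.70 to 5.51) and 6.08 (5.58 to 6.62). By Fisher's exact test the largest of the 4 two-sided p-values was 2.6e-242, for H3K27ac at shared against neuron-only peaks. When an overlap of at least 0.5 of the shorter peak was required, the gap between shared and neuron-only peaks at H3K27ac narrowed from 28.5 to 9.55 percentage points, and the brain-only gap from 38.3 to 25.6. With only the ATAC and H3K27ac peaks of at least the median width, which shortens both lists, the gaps at ATAC narrowed from 46.7 to 22.2 points against neuron-only peaks and from 37.2 to 18.2 points against brain-only peaks. With every peak taken as its midpoint plus and minus 250 bp, all 4 gaps widened. Against neuron-only and brain-only peaks they were then 43.8 and 44.6 points at H3K27ac and 53.1 and 41.2 points at ATAC.

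**Figure D1:**
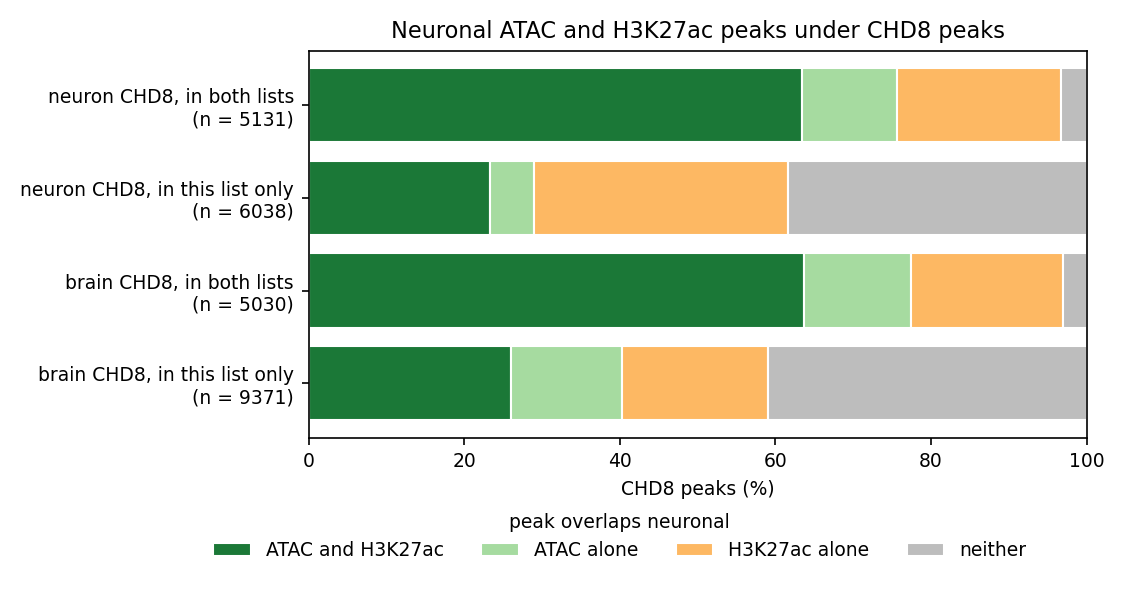
Share of CHD8 peaks (horizontal axis, percent) that overlap a neuronal ATAC peak, a neuronal H3K27ac peak, both or neither, for peaks present in both CHD8 lists and peaks present in the named list only. Both marks were found at 63.4% of shared neuron peaks and at 23.3% of neuron-only peaks.

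Open and acetylated chromatin of the neurons overlapped only in part. Of the 35282 ATAC peaks, 14320 (40.6%, interval 40.1 to 41.1) overlapped an H3K27ac peak, 34.0-fold over shifted peaks (p = 0.001). Of the 39130 H3K27ac peaks, 14295 (36.5%, interval 36.1 to 37.0) overlapped an ATAC peak. CHD8 separated these 2 kinds of open chromatin. Neuron CHD8 was present at 29.9% (interval 29.1 to 30.6) of the acetylated ATAC peaks and at 3.71% (interval 3.46 to 3.98) of the 20962 others, an odds ratio of 11.0 (10.2 to 11.98). Brain CHD8 was present at 38.0% and 7.77%, an odds ratio of 7.29 (6.85 to 7.75), and Fisher's exact test gave a two-sided p of at most 1e-300 for each. With an overlap of at least 0.5 of the shorter peak, 29.01% of ATAC peaks overlapped H3K27ac.

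The widest H3K27ac peaks marked single long acetylated domains. Positions are given in hg19 as listed by the authors, and no gene annotation of that build was used. The widest spanned 29971 bp on chromosome 7 from 96624501 to 96654472, with 2 ATAC peaks, 1 neuron CHD8 peak and 0 brain CHD8 peaks inside. The next were 25113 bp on chromosome 14 (29230300 to 29255413), 22795 bp on chromosome 15 (37382450 to 37405245), 22765 bp on chromosome 5 (87960947 to 87983712) and 14050 bp on chromosome 8 (65279394 to 65293444). Each of these 4 held 1 or 2 ATAC peaks and at most 1 CHD8 peak per tissue. H3K27ac peaks with neuron CHD8 had a median width of 859 bp against 347 bp for those without. Randomly shifted CHD8 peaks also met wide H3K27ac peaks, with a median of 811 bp on average and at most 1126.5 bp over 100 shifts. The median width therefore did not separate CHD8 peaks from shifted ones. Neuron CHD8 was present at 3.94% of H3K27ac peaks of 153 to 226 bp and at 32.1% of those of at least 814 bp. Whether width alone gives that rise was not tested. ATAC peaks were short, with a median of 243 bp. The 5 widest lay on chromosome 17 (73975147 to 73975737), chromosome 9 (77196561 to 77197143), chromosome 4 (99354709 to 99355289), chromosome 6 (26020524 to 26021104) and chromosome 11 (35965501 to 35966080), and were 579 to 590 bp wide. Only the peak on chromosome 17 held neuron CHD8 peaks, 2 of them, and brain CHD8 was present there and at the peak on chromosome 6.

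CHD8 peaks crowded at the edges of the neuronal TADs. Within 20 kb of an edge lay 22.7% (interval 21.96 to 23.5) of neuron CHD8 peaks and 22.5% (interval 21.8 to 23.2) of brain CHD8 peaks, against 6.43% and 6.44% around circularly shifted edges, a 3.53-fold and a 3.50-fold excess. The excess was smaller for ATAC peaks, 11.7% (interval 11.4 to 12.1) or 1.89-fold, and for H3K27ac peaks, 11.6% (interval 11.3 to 11.96) or 1.83-fold. Within the ATAC peaks, those with neuron CHD8 lay near an edge in 26.5% of 5054 cases and the others in 9.28% of 30228, an odds ratio of 3.52 (3.27 to 3.79, Fisher's exact test, two-sided p = 1.7e-221). The excess of neuron CHD8 fell with distance, from 4.59-fold in the first 10 kb to 1.22-fold between 80 and 160 kb and 0.912-fold between 160 and 320 kb. All 4 lists exceeded every shift (one-sided p = 0.001). Edges fall on a 10 kb grid, and 67.3% of the gaps between neighbouring TADs were 10 kb long.

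**Figure D2:**
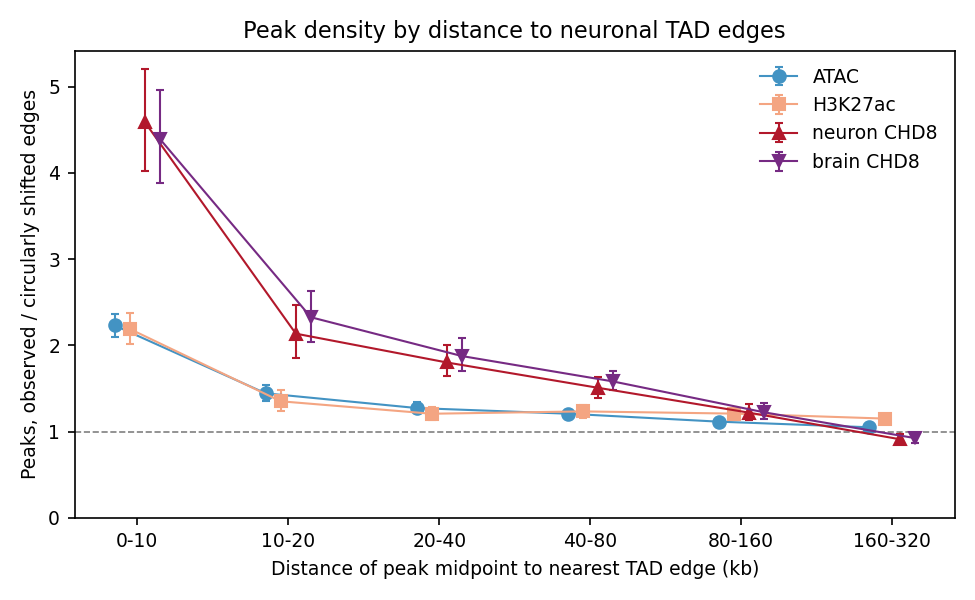
Number of peaks by distance from the peak midpoint to the nearest TAD edge (horizontal axis, kb), divided by the number around circularly shifted edges (vertical axis, ratio). Bars span the ratios to the 2.5 and 97.5 percentiles of 200 shifts, and both CHD8 lists lie above ATAC and H3K27ac in the first 80 kb.

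CHD8 was also unevenly spread over TADs and chromosomes. The 795 shortest TADs, 50 to 280 kb long, held 8.96 neuron CHD8 peaks per Mb, and the 773 longest, 1050 to 7650 kb long, held 1.91. H3K27ac peaks fell from 24.1 to 10.3 per Mb between these groups and ATAC peaks from 16.4 to 10.8. A larger part of a short TAD lies within 20 kb of its edges. The falls with TAD size are therefore not independent of the excess at edges. The 5 TADs with the most neuron CHD8 peaks were chosen after the counts were seen. The first, on chromosome 19 from 57810000 to 58980000, held 51 neuron and 59 brain CHD8 peaks. The others were on chromosome 19 from 36810000 to 38330000 (35 and 45 peaks), chromosome 19 from 52350000 to 54290000 (32 and 37), chromosome 17 from 7120000 to 7610000 (31 and 33) and chromosome 19 from 55600000 to 56170000 (30 and 29). Chromosome 19 as a whole had 14.4 neuron CHD8 peaks per Mb and 55.6 per 100 H3K27ac peaks, where the other autosomes ranged up to 7.98 per Mb and 36.6 per 100, both on chromosome 17. Per 100 ATAC peaks chromosome 19 stood out less, with 77.2 neuron CHD8 peaks against 72.9 on chromosome 22, 67.9 on chromosome 17 and 64.7 on chromosome 16. Across the 1742 TADs of at least 500 kb, which are not independent replicates, neuron and brain CHD8 densities had a Spearman correlation of 0.73 and a Pearson correlation of 0.84, the highest of 6 pairs of lists computed.

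The RNA library carried the transcripts of neurons. Of 23548 gene symbols, 11129 (47.3%) had at least 1 FPKM (fragments normalised for transcript length and library size). The pan-neuronal list had a median of 52.3 FPKM, above all 10000 random gene lists of its size, drawn from all symbols or only from protein-coding ones, and 15 of its 16 members reached 1 FPKM. STMN2, a microtubule regulator of growing axons, stood at 385.0 FPKM, GAP43, a growth cone protein, at 319.3, UCHL1 at 243 and TUBB3, the neuronal beta tubulin, at 186. RBFOX3, which encodes the neuronal nuclear antigen NeuN, was at 0.813. Axon guidance genes were high as well, with a median of 6.99 FPKM (percentile 99.98) and 17 of 20 members at 1 or more. SEMA3C had 47.3 FPKM, NRP2 31.0, ROBO1 26.1 and PLXNA1 19.4, while UNC5A (0.915), SLIT3 (0.668) and UNC5C (0.533) stayed below 1.

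Markers of GABAergic neurons were present, and glutamatergic genes ranged from high to nearly absent. The GABAergic list had 11 of 16 members at 1 FPKM or more and a median of 5.60 (percentile 99.4). GAD2 and GAD1, the enzymes that make GABA, had 9.48 and 9.12 FPKM, and the interneuron transcription factor DLX5 had 8.47. VIP was at 0.00616, and PVALB and NPY were listed at 0. Of the 13 glutamatergic genes, 6 reached 1 FPKM and the median was 0.325 (percentile 31.5). The AMPA receptor subunits GRIA2 (107 FPKM) and GRIA1 (35.8) led it, followed by GRIN2B (5.24) and CAMK2A (4.84), whereas the vesicular glutamate transporter SLC17A7 (0.0910) and the transcription factor NEUROD1 (0.108) were low and NEUROD2 was listed at 0. The other vesicular glutamate transporter SLC17A6 (3.95) and NRN1 (4.42), named after their values were seen, lay above 1. Transcription factors of the cortex reached 1 FPKM in 14 of 16 cases, with a median of 3.27 (percentile 94.0). MEF2C had 56.6 FPKM, FOXP2 29.6 and POU3F3 19.4, while EMX1 (0.116) was low. Genes of other transmitter systems were low, with 2 of 12 at 1 or more and a median of 0.0314 (percentile 3.0). These were DDC (2.86) and ISL1 (2.25), and next came TH at 0.175 and SLC6A4 at 0.0876.

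Genes of synapses and excitability were broadly present. The synapse list had 22 of 25 members at 1 FPKM or more and a median of 5.53 (percentile 99.9), with SYP (37.2), CNTNAP2 (23.7) and HOMER1 (16) among the highest. BSN (0.885), SHANK1 (0.647) and DLGAP2 (0.107) stayed below 1. Of 20 ion channel genes 16 reached 1 FPKM, with a median of 2.12 (percentile 85.4). The sodium channels SCN2A (23.2) and SCN3A (18.2) led, followed by the potassium channel KCND2 (8.94), and KCNA2 (0.368) was low. Of 13 GABA receptor genes 11 reached 1 FPKM, with a median of 4.38 (percentile 96.7). GABRB2 had 25.3 FPKM and GABRA5 12.4, and GABRG3 had 0.851. GABBR1 was at 0.00183, but it belongs to the major histocompatibility complex (MHC) region of chromosome 6, where 25 broadly expressed genes had a median of 0.00549 FPKM. Immediate early genes, which respond to activity, were low apart from JUN (17.9): 3 of 12 reached 1 FPKM, the other 2 being ATF3 (2.66) and IER2 (1.55), followed by JUNB at 0.739, and the median was 0.605 (percentile 41.3).

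**Figure D3:**
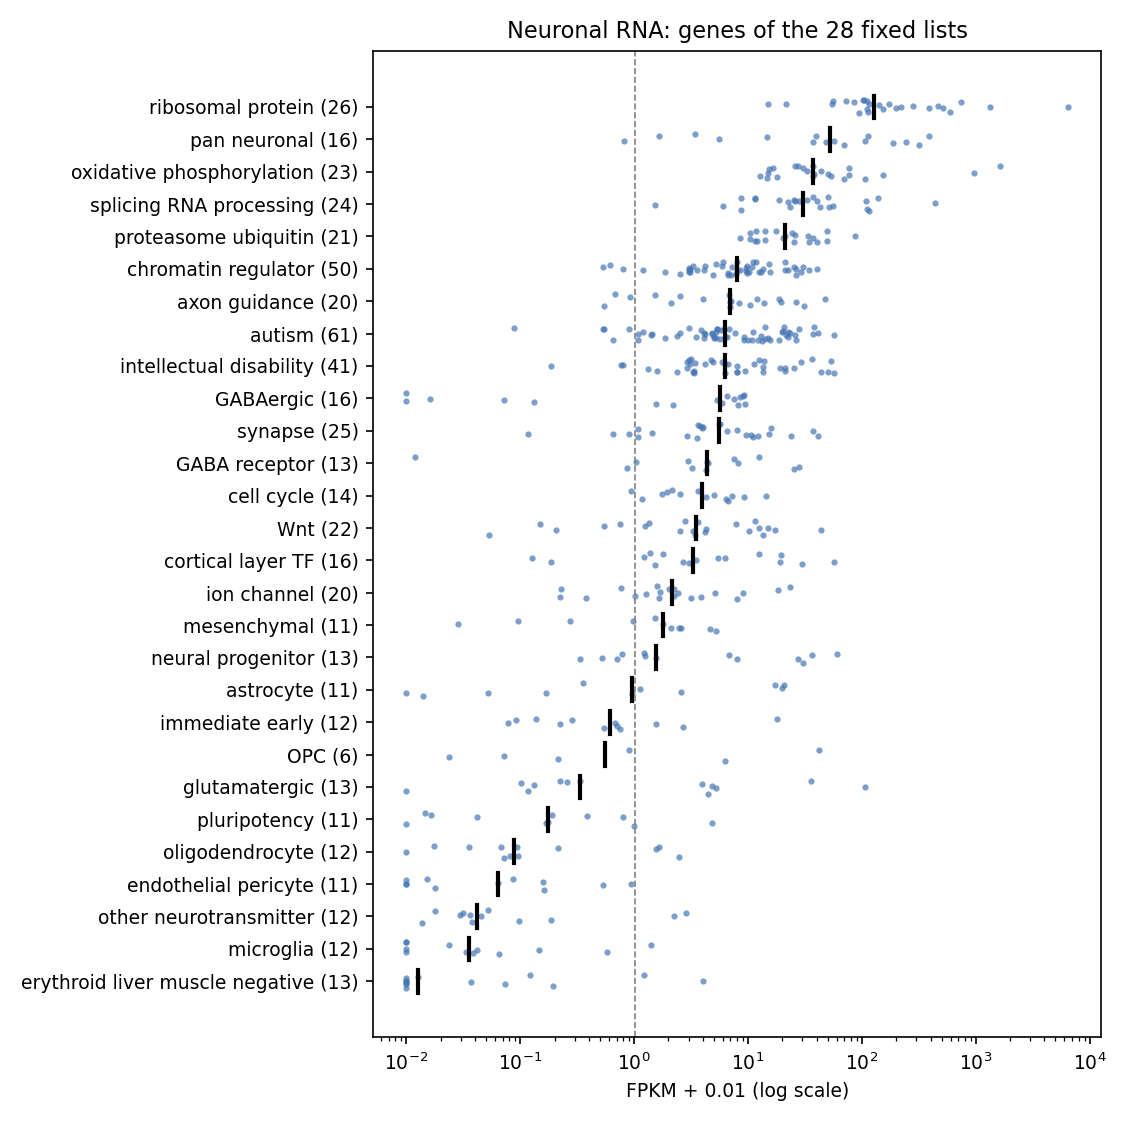
FPKM of each measured gene in the 28 gene lists (horizontal axis, FPKM plus 0.01, log scale), with 1 point per gene, the list median as a black bar, the number of measured genes in brackets and a dashed line at 1 FPKM. Ribosomal protein genes have the highest median and the genes of blood, liver, muscle and skin the lowest.

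Most cell cycle, progenitor and mesenchymal genes reached 1 FPKM, while most markers of glia, vessels, pluripotency and other tissues did not. Of all protein-coding genes, 55.7% reached 1 FPKM. Against random lists of protein-coding genes alone, the progenitor and mesenchymal medians were ordinary (percentiles 49.4 and 54.0), and the cell cycle median lay at 89.6. Of 13 neural progenitor genes 9 reached 1 FPKM, with a median of 1.56 (percentile 70.8), and VIM (60.5), PAX6 (36.5), NES (30.6) and FABP7 (27.7) were the highest. Of 14 cell cycle genes 13 reached 1 FPKM, with a median of 3.92 (percentile 95.8), led by CCNB1 (14.3), TOP2A (9.17), UBE2C (7.19) and CENPF (6.68). Astrocyte genes had a median of 0.940 (5 of 11 at 1 or more, percentile 55.6). GLUL (20.5), the glutamate transporter SLC1A2 (19.8), GJA1 (17.3) and SLC1A3 (2.56) were their highest members. GFAP (0.0424) and AQP4 (0.159) were low and ALDH1L1 was listed at 0, all named after their values were seen. Oligodendrocyte genes had a median of 0.0781 (3 of 12, percentile 8.9), with MBP at 2.48, CNP at 1.63 and MYRF at 0.206. Oligodendrocyte precursor genes had a median of 0.547 (2 of 6, percentile 35.9), with VCAN at 41.8, PTPRZ1 at 6.21, OLIG3 at 0.890 and PDGFRA at 0.204. Microglial genes had a median of 0.0258 (percentile 2.31, or 4.19 without symbols listed at least 5 times, here AIF1), with only CD68 (1.38) at 1 FPKM or more, then P2RY12 (0.569), PTPRC (0.137) and CX3CR1 (0.0549). Vascular genes had a median of 0.0544 (0 of 11, percentile 8.79), the highest being RGS5 (0.935), PDGFRB (0.528), ENG (0.150) and TEK (0.149). Mesenchymal genes had a median of 1.77 (7 of 11, percentile 73.0), led by THY1 (5.26), ACTA2 (4.60), FN1 (2.57) and TAGLN (2.48). Pluripotency genes had a median of 0.166 (1 of 11, percentile 20.5), with LIN28B at 4.83, DNMT3B at 0.987, LIN28A at 0.794 and SALL4 at 0.374. The list of blood, liver, muscle and skin genes had the lowest median, 0.00260 (2 of 13, percentile 0.31), with TTR at 3.98, MYH7 at 1.20, ACTC1 at 0.184 and ALB at 0.112.

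Autism genes and chromatin regulators were expressed almost throughout. Of 61 autism genes 56 reached 1 FPKM, with a median of 6.28 (above every random list), with ILF2 (57.3), UTP6 (38.2) and NCKAP1 (37.4) among the highest. TCF7L2 (0.531), KDM6B (0.524) and ZNF559 (0.0786) were the lowest. CHD8 itself had 10.8 FPKM. All 9 genes of the CHD family lay at 5.87 or more, with CHD3 (28.96), CHD4 (21.3) and CHD2 (15.7) the highest. Intellectual disability genes had a median of 6.25 (38 of 41, above every random list), led by MEF2C (56.6), the RNA helicase DDX3X (53.7), HNRNPU (50.2) and CTNNB1 (43.3), while SETD1A (0.788) and SCN1A (0.750) were below 1. Chromatin regulators had a median of 7.97 (47 of 50, above every random list). The histone demethylase KDM1A had 40.02 FPKM and the remodellers SMARCA1, SMARCA5 and CHD3 had 34.1, 30.1 and 28.96, and the histone methyltransferase genes SETD1A (0.788) and SETD1B (0.599) and the demethylase gene KDM6B (0.524) were below 1. Wnt pathway genes had a median of 3.50 (17 of 22, percentile 97.46), led by CTNNB1 (43.3), WLS (17.1), APC (14.95) and FZD3 (13.5).

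Genes of general cell upkeep were high as a group, the ribosomal protein list above every other and the remaining 3 below the pan-neuronal list. Every measured member reached 1 FPKM among the 26 ribosomal protein genes (median 129), 23 oxidative phosphorylation genes (median 37.3), 24 splicing genes (median 30.2) and 21 proteasome and ubiquitin genes (median 21.1), each above every random list. Among their highest members were RPS27 (6459), RPL7 (737) and RPL19 (595), then COX7C (1622), COX6C (970), COX4I1 (153) and ATP5A1 (107), then HNRNPA1 (436), HNRNPK (138), SF3B1 (116) and HNRNPC (109.6), and UBE2D3 (86.7), SKP1 (49.6), PSMB1 (49.4) and PSMB5 (40.6). In all, 11 of the 28 lists had a median above 97.5% of random lists, the Wnt list falling just short, and 2 lay below 97.5% of them. The second count was 5 with only genes above 0 as background, 5 with only protein-coding genes (median 1.61 FPKM, where all symbols had 0.741) and 1 without symbols listed at least 5 times, while the first stayed at 11. Against protein-coding genes alone the percentiles were lower, such as 12.9 for the glutamatergic, 7.99 for the pluripotency and 90.5 for the Wnt list. Across all genes the 10 highest were MIR3661 (107208 FPKM), SNORA49 (37109), SCARNA21 (35267), RNU11 (20099), SNORD8 (16352), RMRP (12048), TMSB10 (8714), BCYRN1 (7491), SNORD116-1 (7182) and RNU6ATAC (7030). TMSB10, an actin-binding protein, was the only one that codes for a protein. Short non-coding RNA genes held 60.0% of all FPKM, and FPKM divides by length, so values of genes this short are unreliable.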

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

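The alternatives with moved edges, shifts without empty stretches, lists without the MHC region, sums over rows, backgrounds without short RNAs or of protein-coding genes alone and lists without symbols listed at least 5 times were chosen after seeing the data. Across the 17 reported comparisons, 91 of 94 alternative values kept their direction and their side of the threshold or, for counts, stayed within 1.5 times. The 3 exceptions were all the number of gene lists with a median below 97.5% of random lists, which went from 2 to 5 when only genes above 0 or only protein-coding genes formed the background, because random medians are then higher, and to 1 without symbols listed at least 5 times. The share of neuron CHD8 peaks in the brain list ranged from 29.7% to 60.5%, the odds ratio among ATAC peaks from 14.4 to 27.5, their share at ATAC peaks from 25.8% to 69.1%, their share at H3K27ac peaks from 58.3% to 69.2%, and the ATAC share at H3K27ac peaks from 29.01% to 44.0%. The fold of neuron CHD8 near TAD edges ranged from 2.52 with locally moved edges to 4.62 with a window of 10 kb. Of 196 alternative counts for single gene lists, 20 moved by more than 1.5 times, all under another FPKM threshold. A change of background cannot move these counts or the total of list members, since only list members enter them. Keeping the wider peaks leaves the equally wide CHD8 lists whole, so the share of neuron CHD8 peaks in the brain list could not move either. Both tallies therefore include values that were fixed in advance. Summing repeated rows changed 27 of 558 listed genes. A stricter part of the CHD8 lists could not be formed, since they have neither score nor varying width, and chance by bedtools shuffle and the comparisons needing promoters were not run. No paired analysis was possible because no groups with replicates were compared. Depth is unknown, so a peak missing from 1 list cannot be told from one too weak to be called.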

Other observations

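The tests with moved TAD edges, on silence of the MHC region, on acetylated open chromatin at TAD edges and both tests on CHD8 peaks outside ATAC peaks were chosen only after the results, or values close to them, were seen, and so were the histone, MHC and chromosome 17 genes named here.

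Clustered histone genes were abundant in the neuron RNA. Of 70 such genes, 59 had at least 1 FPKM and 48 at least 10, with a median of 29.1. HIST1H4E stood at 2825 FPKM, HIST1H2AE at 574 and HIST1H4H at 376. These transcripts are short and mostly lack poly(A) tails, and the RNA selection is not given in the sources used here.

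The MHC region of chromosome 6, from 29 to 33 Mb, was almost empty in every peak list, with 1 ATAC, 0 H3K27ac, 0 neuron CHD8 and 1 brain CHD8 peaks against 127, 274, 96 and 143 in the flanking 5 Mb on either side. A candidate explanation is that reads were lost because the genome used held several alternative copies of the region: 25 broadly expressed MHC genes had a median of 0.00549 FPKM where 19 upkeep genes elsewhere had 122, and only HLA-B (1.36) and HLA-C (1.26) of the 205 symbols listed at least 5 times reached 1 FPKM (0.976%), against 18.3% of symbols listed 2 to 4 times and 48.1% of those listed once, while genes of a chromosome 17 haplotype were unclear (median 0.620, 3 of 7 at 1 or more). Silence of the region stays open, since it would give the same low RNA values and the bound set for the brain list was wrong by design: that list lay under it, at 0.0175 of the density of its flanks (interval 0.000440 to 0.0990), but both tissues could be silent there. The genome did hold such copies, and the 5 ATAC, 7 H3K27ac, 2 neuron CHD8 and 3 brain CHD8 peaks listed on chromosome 6 haplotype contigs speak against complete silence but are too few to exclude low activity. TADs were called in the region at 2.0 per Mb against 1.8 in the flanks, no biological explanation was tested beyond silence, and values of the list members GABBR1, AIF1, MOG and POU5F1 may not show low expression.

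CHD8 peaks lay near TAD edges more often than ATAC or H3K27ac peaks did. A higher density of peaks in regions rich in edges is argued against as the whole cause by edges moved by only 100 to 500 kb, over which neuron CHD8 still had a 2.52-fold excess (p = 0.001). Open chromatin in general is argued against by the odds ratio of 3.52 between ATAC peaks with and without neuron CHD8, and acetylated open chromatin by an odds ratio of 2.67 (2.44 to 2.92) among acetylated ATAC peaks alone. Promoters, which were not located here, stay open as a source. The hypothesis that CHD8 itself marks TAD edges therefore remains untested against promoter content.

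About as many neuron CHD8 peaks lay outside ATAC peaks (5545) as inside, at an overlap of 1 bp. With every peak taken as its midpoint plus and minus 250 bp, 69.1% overlapped ATAC peaks, so part of the outside peaks lay close to an ATAC peak. False calls spread at random are argued against as the source of all of them, since 55.0% of the outside peaks (interval 53.7 to 56.3) overlapped H3K27ac peaks, against 1.26% by chance. The shifts place peaks anywhere on a chromosome, so false calls that favour active chromatin are not excluded. Fewer, 22.6% (interval 21.5 to 23.7), overlapped a brain CHD8 peak, against 0.225% by chance and 45.9% of all neuron peaks. The 2494 peaks with neither mark are less certain, at 6.94% (interval 5.97 to 8.01) against the 0.195% of shifts. Whether the ATAC list misses active sites unevenly along the genome could not be told. The share of the 4242 shared acetylated sites with an ATAC peak differed by 14.9 percentage points between the lowest and the highest autosome. A permutation test of the variation over all autosomes, not of this range, gave p = 0.36. For those sites a difference between autosomes cannot be told apart from counting error. Over all peaks, ATAC peaks per 100 H3K27ac peaks ran from 45.1 on chromosome 22 to 140 on chromosome 4.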
